A study of Homo sapiens with 8 samples.

How the data were processed

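The data are RNA-seq profiles of MCF7 and SKBR3 breast cancer cells, transfected with siRNA against AKTIP or mock-transfected for 72 h, with 2 biological replicates in each of 4 groups. Per the labels' protocols, total RNA was extracted with TRIzol, 2 ug was used with the KAPA Stranded mRNA-Seq kit, and libraries were sequenced on a NovaSeq 6000. Per the submitters' processing notes, the authors used STAR 2.5.2 and DESeq2 1.26.0 with the GRCh38 (hg38) genome. Per the file headers, each deposited file lists the estimated count (expected count) of every gene in 1 library, with the posterior standard deviation of that count and gene lengths. The headers have the form that RSEM writes, but the quantifier, the annotation release and the strand setting are not given in the sources used here. A gene and its antisense partner may therefore share reads. Multi-mapped reads are split between genes in such estimates, so the values of near-identical genes are uncertain. The sequence of the siRNA is not given either, and the labels name no non-targeting siRNA.

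Each file listed 60725 genes. The 50 pseudoautosomal copies on the Y chromosome were added to their X copies, which left 60675 genes, and the estimated counts were then rounded to whole numbers. Of these, 57055 took names and GRCh38 coordinates from GENCODE release 29; 3620 matched no name and kept their identifiers. Library totals were 21818107 to 24994484. At that depth, replicates of a group differed across genes by 1.86 to 2.77 times the variance of Poisson counting. The SEs of the fold changes of single genes come from replicates, not from counting alone. Intervals of odds ratios and SEs of list means are taken across genes, so they do not cover variation between cultures.

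The main test was edgeR 4.0.16 (R 4.3.3): filterByExpr by group with its minimum count of 10, TMM scaling, and robust glmQLFit with glmQLFTest on all 8 libraries in 1 fit of 4 groups, with 4 residual degrees of freedom. The contrasts were siAKTIP minus mock in MCF7, the same in SKBR3, and the difference of these (MCF7 minus SKBR3). Tests were two-sided, and a Benjamini-Hochberg adjusted p under 0.05 over 16859 genes counted as changed. CPM values are scaled by TMM, and the SE of a log2 fold change was derived from the quasi-likelihood F statistic. Both lines have their own controls, so the 2 contrasts share no library.

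38 gene lists were set, and 37 were tested with limma 3.58.1, by camera on log2 CPM (prior count 2, correlation 0.01) and by fry, with Benjamini-Hochberg adjustment over these 37, which had at least 5 measured genes. AKTIP was left out of every list test. Counts within a list are given both over all genes and adjusted over the list alone. The lists, the tests and the rule for naming genes were set before the data were examined. The rule took, per line, the 10 genes with the largest increase and the 10 with the largest decrease among those with an adjusted p under 0.05, at least 5 CPM, non-overlapping replicates and a gene symbol. It also took the 6 genes of smallest adjusted p in the interaction test, up to 4 members of each list discussed, and AKTIP, ESR1, PGR, GREB1, TFF1, ERBB2, JAK2, STAT3, SOCS3, CAND1 and CUL2.

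Alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, no low-count filter, only the libraries of a line, the replicate number as a block, a 2-fold threshold (for counts of genes only), another prior count, an estimated correlation and fry (for lists only), and each library left out in turn. Where a library was left out, the lone library of that group was assumed to vary like the other groups.

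For the search for short motifs, the longest 3' UTR of each protein-coding gene in GENCODE release 29 (at least 50 nt) was scanned for all 16384 heptamers. Log2 fold changes of genes of at least 5 CPM were ranked after UTR length and GC content were regressed out, and carriers of each heptamer (at least 50) were compared with the other genes by a one-sided rank-sum z with Bonferroni adjustment over the heptamers of a line and direction. Genes without such a UTR were not searched. Odds ratios were pooled by Mantel-Haenszel over 5 classes of UTR length and 3 of expression, with 95% intervals. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used.

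The steps were tested on simulated data. With counts simulated for the MCF7 comparison (16595 genes), edgeR recovered 74%, 96%, 98% and 100% of 50 genes each changed 1.2, 1.5, 2 and 3-fold, with 10 false calls, and DESeq2 54%, 88%, 98% and 100%, with 5. The changed genes were drawn only from those of at least 5 CPM in both lines, so recovery at lower expression was not simulated. In 5 simulations of the same libraries without any change, edgeR called 2 to 16 genes per contrast. Every contrast thus held false calls, more than an adjusted p under 0.05 should allow when nothing changed. The counts of changed genes may include such calls. A planted list of 30 genes, each raised at least 1.5-fold, had a camera adjusted p of 1.92e-65, and 0 of 30 unchanged lists were called in the MCF7 simulation. Genes were simulated independently of each other. The simulation therefore shows neither the power for smaller shifts nor the rate of false calls among lists of correlated genes. In the motif search (10150 genes of the MCF7 comparison), a planted shift of -0.10 ranked first in 20 of 20 runs, and 2 of 20 shuffles held a heptamer with an adjusted p under 0.05.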

Results

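Transcript levels were measured by RNA sequencing in MCF7 and SKBR3 cells transfected with a small interfering RNA (siRNA) against AKTIP, or mock-transfected, for 72 h. MCF7 is an estrogen receptor-positive, luminal breast cancer line, and SKBR3 is an estrogen receptor-negative line with ERBB2 (HER2) amplification. Each of the 4 groups (MCF7 mock, MCF7 siAKTIP, SKBR3 mock and SKBR3 siAKTIP) had 2 biological replicates, which gave 8 libraries. Estimated counts summed to between 21818107 and 24994484 per library, and 16859 genes passed the low-count filter. Replicates of a group correlated across genes with Pearson's r between 0.992 and 0.993 on the log2 CPM scale, and the biological coefficient of variation of the joint fit was 3.25%. The mitochondrially encoded share of counts was 7.17% and 7.15% in MCF7 mock and 7.17% and 7.06% in MCF7 siAKTIP libraries. In SKBR3 it was 9.36% and 9.31% in mock and 9.004% and 8.857% in siAKTIP libraries. The labels call the control cells mock-transfected and name no non-targeting siRNA, so effects of siRNA uptake itself and of AKTIP loss are not separated in any difference between these groups.

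AKTIP encodes a ubiquitin-conjugating enzyme variant that joins Hook proteins and FHIP in a dynein adaptor complex. It is annotated as ENSG00000166971.16 on the minus strand of chromosome 16, from 53491040 to 53504411 of GRCh38. In MCF7 it stood at 26.9 ± 1.70 CPM in mock and 4.43 ± 0.638 CPM in siAKTIP cells (mean ± SD, n = 2), a log2 fold change of -2.60 ± 0.10 (SE) that left 16.5% of the mock level (edgeR quasi-likelihood test, adjusted p = 4.08e-21). In SKBR3 it stood at 84.4 ± 1.90 CPM in mock and 25.4 ± 2.63 CPM in siAKTIP cells, a log2 fold change of -1.73 ± 0.07 that left 30.1% (adjusted p = 1.81e-20). The reduction was larger in MCF7 than in SKBR3, by a log2 difference of -0.87 ± 0.13 in the interaction test (adjusted p = 2.24e-04). In each line both siAKTIP libraries lay below both mock libraries, as their labels state.

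**Figure D1:**
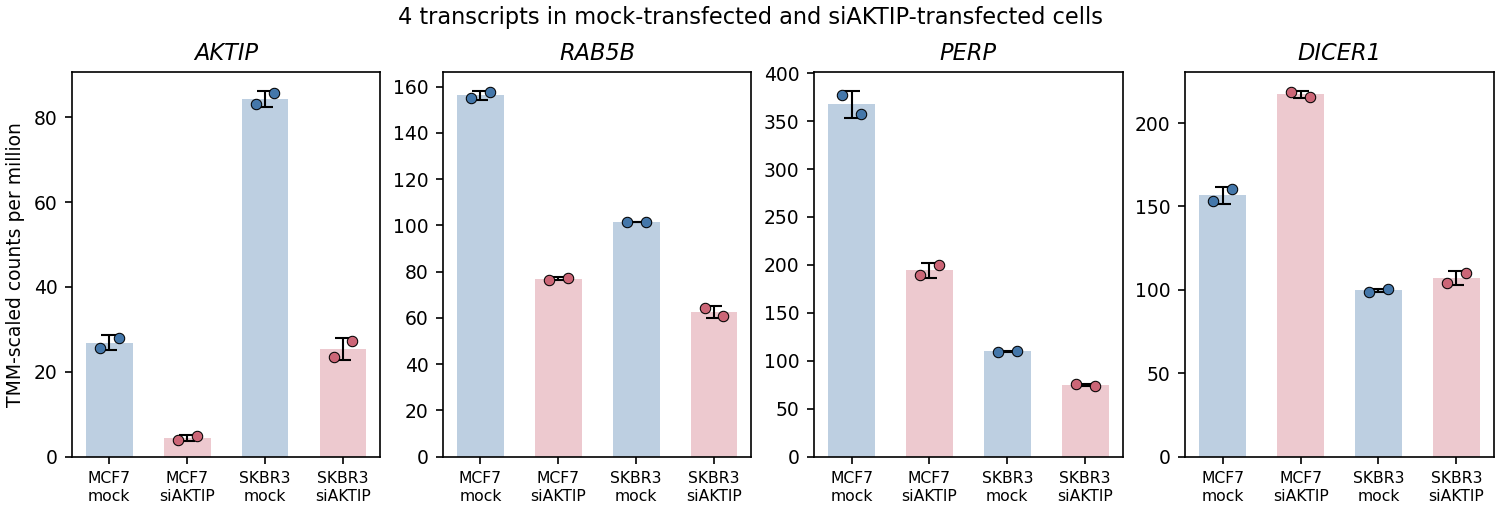
TMM-scaled CPM (vertical axes, starting at 0) of AKTIP, RAB5B, PERP and DICER1 in the 4 groups. Points are the 2 libraries of a group, bars their mean and whiskers the SD; AKTIP stands at 4.43 CPM in MCF7 siAKTIP and 25.4 CPM in SKBR3 siAKTIP cells.

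The first comparison asked how AKTIP depletion changes the transcriptome of an estrogen receptor-positive line. Beside AKTIP, and among named genes of at least 5 CPM, the steepest reductions in MCF7 were in NNT, the mitochondrial transhydrogenase that makes NADPH (58.6 ± 2.74 to 18.1 ± 0.0409 CPM, log2 fold change -1.69 ± 0.08, adjusted p = 9.39e-20; 0.123 CPM in SKBR3 mock cells), and RAB5B, a GTPase of early endosomes (156.3 ± 1.94 to 77.0 ± 0.530 CPM, -1.02 ± 0.04, adjusted p = 7.79e-23). PERP, a membrane protein of desmosomes and a p53 effector, fell to 52.9% of mock (-0.92 ± 0.04, adjusted p = 1.21e-21). ARPC4, a subunit of the actin-nucleating Arp2/3 complex, fell to 56.2% (-0.83 ± 0.05, adjusted p = 1.32e-15). RWDD4 (-0.94), MT2A (-0.93), the transcription factor GLIS2 (-0.88), the ceramide kinase CERK (-0.76) and the galactosyltransferase B3GALT6 (-0.75) completed the 10 lowest at that level. MT2A belongs to the near-identical metallothionein genes, so its reads may be shared with relatives, and its call was lost without mock replicate 1 or mock replicate 2. The 10 highest at that level were STRADB (0.81 ± 0.11, a pseudokinase related to the LKB1 activator STRAD), SERPINA5 (0.77), SPOCK1 (0.64), SH3D21 (0.60), the hydroxylase FAXDC2 (0.56), NAV2 (0.53), the collagen receptor MRC2 (0.52), the calpain CAPN8 (0.49), the matrix Gla protein MGP (0.49) and the actin-binding cofilin CFL2 (0.48).

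Over all genes, 679 of 16859 differed in MCF7 (334 higher and 345 lower, two-sided edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with a median fold change of 1.16 among them. Of these, 17 changed at least 2-fold (7 higher and 10 lower). Only AKTIP, NNT and RAB5B among the 17 had at least 5 CPM, non-overlapping replicates and a gene symbol. The DESeq2 Wald test called 424 genes. Of 88 calls of named genes, 33 held in every alternative run on single genes, which leaves out the 2-fold threshold. The count of changed genes was 444 without mock replicate 1, 350 without siAKTIP replicate 1 and 312 without siAKTIP replicate 2.

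**Figure D2:**
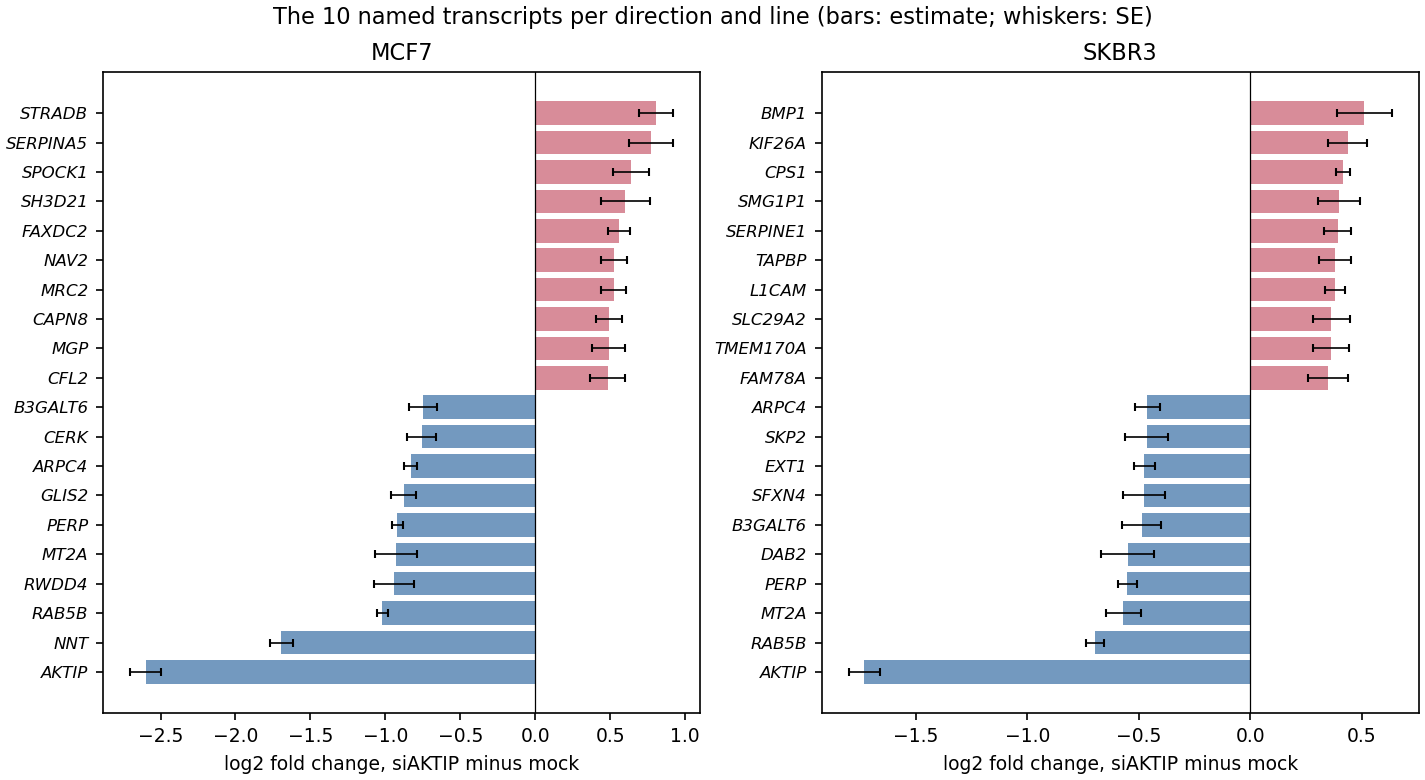
Log2 fold changes (horizontal axes) of the 10 transcripts with the largest increase and the 10 with the largest decrease in MCF7 (left) and SKBR3 (right), among changed genes with a symbol, at least 5 CPM and non-overlapping replicates. Bars are the estimates and whiskers the SE; AKTIP is the lowest bar in both lines, at -2.60 and -1.73.

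Among the gene lists fixed beforehand, the small-RNA silencing machinery had the smallest camera p in MCF7. Of its 13 measured genes, 4 rose and 0 fell, and adjusted over the list alone 7 rose and 0 fell. They were DICER1, which cuts microRNA precursors (0.47 ± 0.04, adjusted p = 4.43e-12), the Argonaute partners TNRC6A (0.34 ± 0.04) and TNRC6B (0.17 ± 0.05), and the Argonaute AGO2 (0.16 ± 0.03). The list was called higher by camera (adjusted p = 4.91e-04, and adjusted p = 0.368 with an estimated correlation). TNRC6B was lost with the DESeq2 Wald test and, like AGO2, without single MCF7 libraries.

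Estrogen receptor-induced genes were the other list called higher in MCF7 (adjusted p = 0.0194, and adjusted p = 0.467 with an estimated correlation). Of 50 measured members, 11 rose and 0 fell, and adjusted over the list alone 16 rose and 5 fell. The cadherin CELSR2 (1328 to 1597 CPM, log2 fold change 0.27 ± 0.03), the kinase SGK3 (0.46 ± 0.06), the cyclin CCND1 (926 to 1058 CPM, 0.19 ± 0.03) and the chemokine CXCL12 (0.27 ± 0.04) were among them. GREB1, PGR and TFF1, also targets of the receptor, did not pass the test. GREB1 stood at 1367 ± 9.33 CPM in mock and 1389 ± 2.05 CPM in siAKTIP cells (0.02 ± 0.03), PGR at 138.1 ± 3.75 and 140.4 ± 6.09 CPM (0.02 ± 0.04), and TFF1 at 808.6 ± 8.68 and 886.7 ± 31.0 CPM (0.13 ± 0.05, adjusted p = 0.197). ESR1, the receptor itself, stood at 299.3 ± 8.23 and 321.4 ± 9.40 CPM (0.10 ± 0.04, adjusted p = 0.221). Of 13 measured genes of the receptor's machinery, edgeR called 0 and DESeq2 0, with 3 at an unadjusted p under 0.05. The list of induced genes was not called without mock replicate 2 (adjusted p = 0.155), siAKTIP replicate 1 (0.0586) or siAKTIP replicate 2 (0.196), within a range over the alternatives of 0.0151 to 0.467.

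5 lists were called lower in MCF7. Genes of G1/S and DNA replication had a median log2 fold change of -0.08 (adjusted p = 0.00308, and adjusted p = 0.467 with an estimated correlation); 3 of 50 fell, namely the thymidine kinase TK1 (-0.22 ± 0.05), the flap endonuclease FEN1 (-0.21 ± 0.05) and the helicase subunit MCM4 (-0.13 ± 0.04), and adjusted over the list alone also 3. Of 50 G2/M genes 2 fell, the kinetochore subunit SPC24 (-0.56 ± 0.08) and the mitotic transcription factor FOXM1 (-0.19 ± 0.04), and the spindle protein ASPM rose (0.23 ± 0.04); adjusted over the list alone, 4 fell and 1 rose (adjusted p = 0.043, and adjusted p = 0.638 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 2 of 36 lower, COX5B (-0.20 ± 0.04) and NDUFS3 (-0.18 ± 0.05), and 3 adjusted over the list alone (adjusted p = 0.0112, and adjusted p = 0.615 with an estimated correlation). Cytosolic ribosomal proteins had 1 of 70 lower, RPS20 (-0.15 ± 0.03), and 1 adjusted over the list alone (adjusted p = 0.0163, and adjusted p = 0.74 with an estimated correlation). In the integrated stress and unfolded protein response, 4 of 32 fell, among them the chaperone HSPA5 (-0.14 ± 0.02), HERPUD1 (-0.15 ± 0.03) and DDIT4 (-0.15 ± 0.04), and EDEM1 rose (0.17 ± 0.05); adjusted over the list alone, 7 fell and 2 rose (adjusted p = 0.0194, and adjusted p = 0.615 with an estimated correlation). In all, camera called 7 of 37 lists in MCF7 and fry called 5. The lists called by both were the silencing machinery and estrogen receptor-induced genes. None of the 5 lower lists was called by fry (adjusted p between 0.0799 and 0.362), which instead called the Hook, FHIP and dynein adaptors (0.0471), the HOPS, CORVET and endosomal fusion genes (0.0471) and the lamins and nuclear envelope genes (0.0314). The number of lists called was 3 without mock replicate 1 and 2 without siAKTIP replicate 2. Without either of these libraries, oxidative phosphorylation, ribosomal proteins, the stress response and G2/M genes were no longer called, and G2/M genes were also lost without mock replicate 2; G1/S genes and the silencing machinery kept their calls without any single library.

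**Figure D3:**
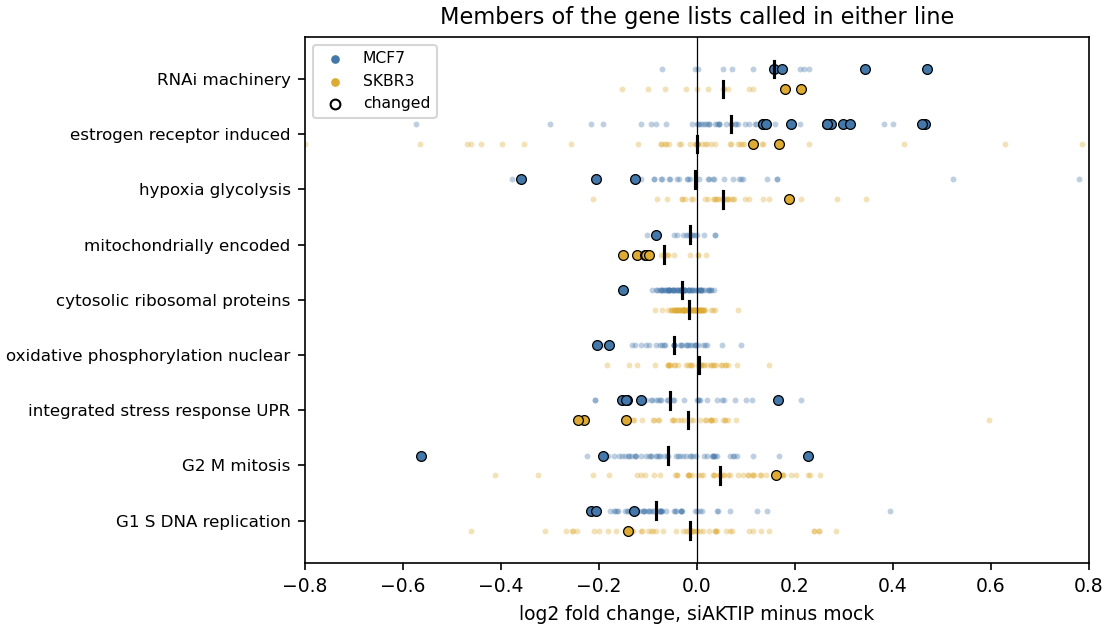
Log2 fold changes (horizontal axis, from -0.8 to 0.8) of the members of the 9 gene lists called in either line. Each point is a gene, outlined points passed the test, short vertical lines are medians and 7 values lie outside the axis; outlined members of the small-RNA silencing machinery lie to the right of 0.

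Transcripts of JAK2-STAT3 signalling and cullin ligases, which have been linked to AKTIP in breast cancer, were examined next in MCF7. Only RNA was measured, so signalling and ligase activity are not covered. Over all genes, 4.03% were called in MCF7. JAK2 stood at 25.6 ± 1.08 CPM in mock and 27.2 ± 2.28 CPM in siAKTIP cells (0.09 ± 0.08), STAT3 at 136.3 and 131.2 CPM (-0.06 ± 0.04), and SOCS3, a feedback inhibitor induced by STAT3, at 2.27 and 2.47 CPM (0.12 ± 0.23); none of these 3 genes passed the test. Of 18 JAK-STAT components 1 rose, the STAT3 inhibitor PIAS3 (0.13 ± 0.03), and 1 rose adjusted over the list alone. Of 28 STAT3 targets 3 rose, SERPINA3 (0.46 ± 0.10), CCND1 (0.19 ± 0.03) and HIF1A (0.12 ± 0.03), and adjusted over the list alone 3 rose and 3 fell; the median of these targets was -0.01 while camera's direction was up. CAND1 (0.01 ± 0.04), the exchange factor of cullin ligases, and CUL2 (0.06 ± 0.06) did not pass. Of 42 cullin ligase genes 1 fell, the F-box protein SKP2 (-0.61 ± 0.10), and 1 adjusted over the list alone. In the Hook, FHIP and dynein adaptor list, without AKTIP, HOOK3 rose (0.27 ± 0.06) and the dynactin subunit DCTN2 fell (-0.14 ± 0.04); adjusted over the list alone, 2 rose and 1 fell. Among 34 p53 targets, CCNG1 (0.20 ± 0.03) and TNFRSF10B (0.14 ± 0.04) rose, and 2 rose adjusted over the list alone. Of 31 type I interferon response genes, edgeR called 0 and DESeq2 1, with 7 at an unadjusted p under 0.05. None of these 6 lists was called by camera. Among markers of other cell types, edgeR and DESeq2 called 0 of 4 measured fibroblast genes, too few for a list test, and 0 of 6 immune and endothelial genes, with 2 and 0 at an unadjusted p under 0.05; the latter list was not called. Of 17 basal and mesenchymal markers FN1 (0.28 ± 0.05) and TGFBI (0.37 ± 0.07) rose and CAV1 fell (-0.31 ± 0.05), and adjusted over the list alone 3 rose and 2 fell.

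The second comparison asked the same question in the estrogen receptor-negative, HER2-amplified line. RAB5B was again among the lowest transcripts beside AKTIP (101.5 ± 0.00834 to 62.7 ± 2.54 CPM, log2 fold change -0.70 ± 0.04, adjusted p = 2.38e-15). So was PERP (109.9 ± 0.434 to 74.9 ± 1.00 CPM, -0.55 ± 0.04, adjusted p = 6.18e-12). MT2A (-0.57), the endocytic adaptor DAB2 (-0.55), B3GALT6 (-0.49), SFXN4 (-0.48), the heparan sulfate polymerase EXT1 (-0.47), SKP2 (-0.47) and ARPC4 (-0.46) completed the 10 lowest named genes of at least 5 CPM. The increase with the smallest adjusted p was in CPS1, the first enzyme of the urea cycle, from 663.1 ± 8.03 to 884.3 ± 46.7 CPM (0.42 ± 0.03, adjusted p = 1.77e-11). BMP1 (0.51 ± 0.12), KIF26A (0.44), the pseudogene SMG1P1 (0.40), the plasminogen activator inhibitor SERPINE1 (0.39 ± 0.06), the antigen-processing protein TAPBP (0.38), the adhesion molecule L1CAM (0.38 ± 0.05), the nucleoside transporter SLC29A2 (0.36), TMEM170A (0.36) and FAM78A (0.35) were the other 9 of the 10 highest at that level. SMG1P1 is a near copy of SMG1, so its value is uncertain, and its call was lost without any of 5 libraries (MCF7 mock 1 or 2, SKBR3 mock 2, SKBR3 siAKTIP 1 or 2). The MT2A call was lost without MCF7 mock 1, MCF7 mock 2 or SKBR3 mock 1.

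In SKBR3, 177 of 16859 genes differed (97 higher and 80 lower, edgeR quasi-likelihood test), and 12 of them changed at least 2-fold (7 higher and 5 lower). Only AKTIP among the 12 had at least 5 CPM, non-overlapping replicates and a gene symbol. With DESeq2's size factors the split moved from 54.8% higher to 67.0% higher, with 134 higher and 66 lower. Of 46 calls of named genes, 11 held in every alternative run on single genes. The count of changed genes was 68 without mock replicate 1, 77 without mock replicate 2, 94 without siAKTIP replicate 1 and 91 without siAKTIP replicate 2.

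3 lists were called in SKBR3, each with an adjusted p = 0.987 with an estimated correlation, and fry called 0. Neither the fit with the replicate number as a block nor the fit without a low-count filter called any of them. Mitochondrially encoded genes were lower (adjusted p = 0.0218): 5 of 15 fell, among them the cytochrome oxidase subunits MT-CO1 (-0.11 ± 0.02) and MT-CO3 (-0.10 ± 0.02), MT-ATP8 (-0.15 ± 0.03) and MT-ND3 (-0.12 ± 0.03), and 9 fell adjusted over the list alone. DESeq2 called 2 of the 15; MT-CO1 and MT-CO3 lost their calls in its Wald test, and MT-CO3 and MT-ND3 with its size factors. The mitochondrial share of counts was also lower in both siAKTIP than in both mock libraries, as given above. Hypoxia and glycolysis genes were higher (adjusted p = 0.0288): 1 of 32 rose, the lactate dehydrogenase LDHA (0.19 ± 0.03), and 2 adjusted over the list alone. G2/M genes were higher (adjusted p = 0.0321): 1 of 50 rose, the phosphatase CDC25B (0.16 ± 0.04), and 3 adjusted over the list alone. No list was called without mock replicate 1 or siAKTIP replicate 2, and 1 was called without siAKTIP replicate 1. Hypoxia and glycolysis genes lost their call without any 1 of the SKBR3 libraries. G2/M genes also lost theirs without SKBR3 mock replicate 2 (adjusted p = 0.433), MCF7 siAKTIP replicate 1 (0.0556) or MCF7 siAKTIP replicate 2 (0.0579), within a range over the alternatives of 8.74e-05 to 0.988.

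Estrogen receptor genes were barely expressed in SKBR3, with ESR1 at 1.70 CPM in mock and 1.38 CPM in siAKTIP cells, and PGR, GREB1 and TFF1 under 1 CPM. Of 50 estrogen receptor-induced genes, CELSR2 (0.17 ± 0.03) and CCND1 (0.11 ± 0.03) rose and 0 fell, and adjusted over the list alone 6 rose and 2 fell. Of 13 genes of the receptor's machinery edgeR and DESeq2 called 0, with 2 at an unadjusted p under 0.05. ERBB2, the amplified receptor, stood at 12960 CPM in mock and 12980 CPM in siAKTIP cells (0.00 ± 0.02), and in MCF7 at 90.1 ± 3.45 and 85.1 ± 1.68 CPM (-0.08 ± 0.03, adjusted p = 0.113). JAK2 (-0.25 ± 0.10), STAT3 (-0.02 ± 0.03), SOCS3 (0.35 ± 0.21), CAND1 (0.05 ± 0.04) and CUL2 (-0.03 ± 0.06) did not pass the test. The interleukin-6 receptor IL6R rose (256.3 to 294.9 CPM, 0.20 ± 0.04), the only 1 of 18 JAK-STAT components to do so, also adjusted over the list alone. CCND1 was the only 1 of 28 STAT3 targets to change, against 4 that rose and 2 that fell adjusted over the list alone. AGO2 (0.21 ± 0.04) and TNRC6A (0.18 ± 0.04) rose among 13 genes of small-RNA silencing, which as a list were not called (adjusted p = 0.331). SKP2 fell among 42 cullin ligase genes, CCNG1 rose among 34 p53 targets (0.27 ± 0.05) and CDC6 fell among 50 G1/S genes (-0.14 ± 0.03). Adjusted over the list alone, 3 rose and 1 fell in the silencing machinery, 1 fell among cullin ligase genes, 1 rose and 2 fell among p53 targets, and 4 fell among G1/S genes. AKTIP was the only member of the Hook, FHIP and dynein adaptor list that changed. In the integrated stress and unfolded protein response, 3 of 32 genes fell, among them DDIT4 (-0.15 ± 0.03), and 5 adjusted over the list alone. Nuclear oxidative phosphorylation and cytosolic ribosomal proteins had 0 genes called by edgeR and DESeq2, with 3 of 36 and 2 of 70 at an unadjusted p under 0.05. Of 31 interferon response genes edgeR and DESeq2 called 0, with 1 at an unadjusted p under 0.05. SERPINE1 and the integrin ITGA5 (0.25 ± 0.06) rose among 17 basal and mesenchymal markers, and 2 rose adjusted over the list alone. Of 4 fibroblast and 6 immune and endothelial genes, edgeR and DESeq2 called 0, with 1 and 0 at an unadjusted p under 0.05.

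The third comparison set the responses of both lines side by side. 21 genes rose in both lines, against 1.92 for independent lists of these sizes, and 27 fell in both, against 1.64 (two-sided Fisher's exact tests, p = 2.34e-16 and p = 5.19e-26). The tests take genes as independent and as equally likely to be called in each line, although some are barely expressed in 1 line. Both contrasts also share 1 estimate of the spread. The p values therefore do not measure how the overlap would vary between cultures. The genes that fell in both included AKTIP, RAB5B, PERP, ARPC4, MT2A, B3GALT6, SFXN4, EXT1, SKP2, ESYT2 and the co-chaperone BAG3 (-0.21 and -0.26). The genes that rose in both included CCND1, CELSR2, CCNG1, TNRC6A and AGO2. Across the 9259 genes of at least 5 CPM in both mock groups the fold changes correlated with Pearson's r of 0.18 and Spearman's rho of 0.148, and across all 16859 genes with an r of 6.77e-04 and a rho of 0.0744, where genes are not independent replicates. The count of 48 shared genes was 29 without MCF7 siAKTIP replicate 1 or 2, 22 without SKBR3 mock replicate 1, 28 without SKBR3 mock replicate 2 and 31 without SKBR3 siAKTIP replicate 2.

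**Figure D4:**
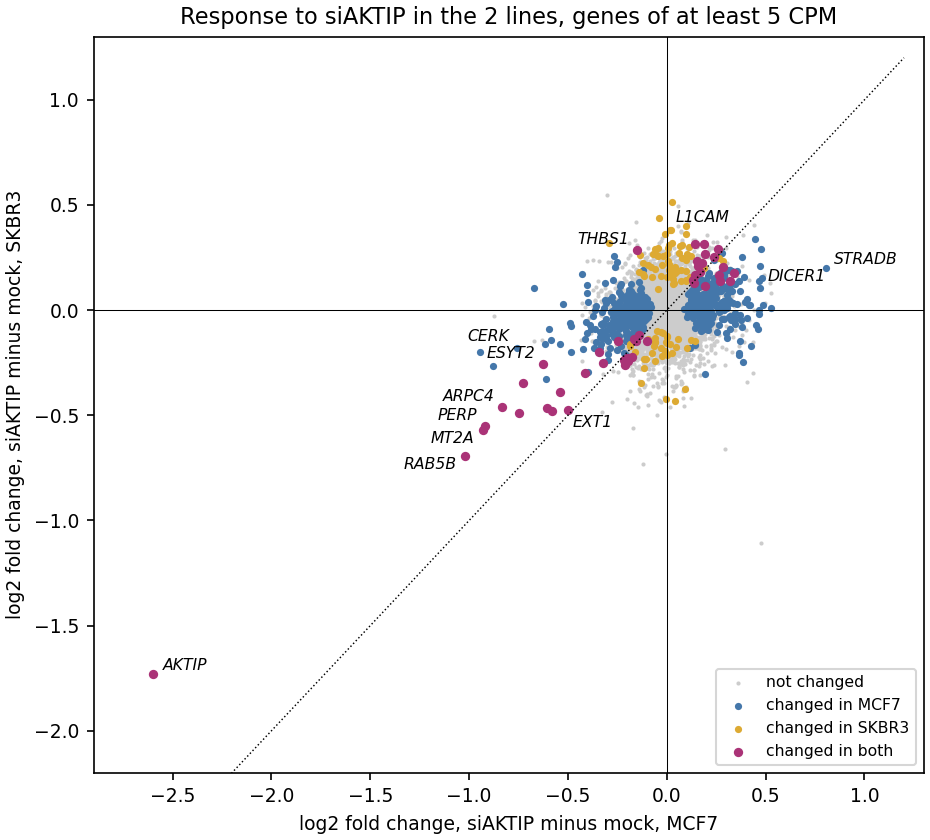
Log2 fold change after siAKTIP in MCF7 (horizontal axis) against SKBR3 (vertical axis) for 9259 genes of at least 5 CPM, coloured by the line in which they changed; 3 genes lie outside the axes. The dotted line marks equal change, and AKTIP, RAB5B and PERP lie above it at the lower left, with the larger decrease in MCF7.

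The interaction test found 139 genes whose response differed between the lines, 62 with the higher value in MCF7 and 77 with the higher value in SKBR3. The matrix glycoprotein THBS1 fell in MCF7 (1196 to 1079 CPM, -0.15 ± 0.03) and rose in SKBR3 (46.2 to 56.3 CPM, 0.29 ± 0.04), the only gene called in opposite directions (difference -0.43 ± 0.05, adjusted p = 6.41e-07). The calpain CAPN2 (difference 0.45 ± 0.05, adjusted p = 2.24e-06) and the collagen COL12A1 (0.42 ± 0.06, adjusted p = 3.24e-05) rose in MCF7 and did not pass in SKBR3. ACTG1, a cytoskeletal actin, rose in SKBR3 (0.20 ± 0.02) and did not pass in MCF7 (-0.06 ± 0.02; difference -0.26 ± 0.03, adjusted p = 1.56e-05). ESYT2, a tether between endoplasmic reticulum and plasma membrane, fell in both lines and more in MCF7 (difference -0.37 ± 0.05, adjusted p = 7.04e-05). DICER1 rose in MCF7 by 0.47 and stood at 0.11 ± 0.04 in SKBR3 (difference 0.36 ± 0.05, adjusted p = 1.67e-04). G2/M genes were the only list called by the interaction test (adjusted p = 0.00133, and adjusted p = 0.872 with an estimated correlation), with CDC25B the 1 of 50 genes to differ and 3 adjusted over the list alone. The count of 139 was 216 without MCF7 mock replicate 2, 83 and 65 without MCF7 siAKTIP replicates 1 and 2, 73 and 65 without SKBR3 mock replicates 1 and 2, and 75 without SKBR3 siAKTIP replicate 1.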

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

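The tests below on genes with the heptamer, on independently chosen genes and on separate fits of each line were chosen only after results were seen; the prediction on the slope was written after the fold changes of single genes had been seen and before its test was run. 139 genes responded differently in MCF7 and SKBR3 by the interaction test of edgeR, and the following named ones were among them. Values are the log2 difference of the responses, MCF7 minus SKBR3. The difference was negative for AKTIP (-0.87), THBS1 (-0.43), ESYT2 (-0.37), PERP (-0.37), ARPC4 (-0.37), RAB5B (-0.33) and ACTG1 (-0.26). It was also negative for the carbamoyl phosphate synthase CPS1 (-0.77), the transcription factor GLIS2 (-0.61), RWDD4 (-0.75), the ceramide kinase CERK (-0.58), the lysosomal protease CTSZ (-1.02), TAPBP (-0.36) and L1CAM (-0.36). Negative differences were also found for the stress-responsive NDRG1 (-0.38), the phosphatase CDC25B (-0.28), the chaperone HSPA5 (-0.20), the keratins KRT19 (-0.19) and KRT8 (-0.15), and the glycolytic enzyme TPI1 (-0.19). CTSZ stood at 2.16 CPM in MCF7 mock cells and MRC2 at 0.811 CPM in SKBR3 mock cells, close to the filter. The difference was positive for MRC2 (1.82), STRADB (0.60), the immediate early gene EGR1 (0.58), NAV2 (0.52), SGK3 (0.46), CAPN2 (0.45), COL12A1 (0.42), DICER1 (0.36), HOOK3 (0.34) and the chromatin remodeller CHD9 (0.24). Among the gene lists, G2/M genes differed between the lines, with a camera adjusted p of 0.00133, but not with an estimated correlation (adjusted p = 0.872) or by fry (adjusted p = 0.416).

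Fewer genes changed in SKBR3 than in MCF7, 177 against 679, with a like median fold change among them, 1.17 against 1.16. Lower precision does not account for the gap: with each line fitted alone, the median standard error in SKBR3 was 1.006 times that of MCF7 over 8851 genes, and 246 and 682 genes were called. A lower dose or uptake of the siRNA could scale all responses alike. It would then give the ratio of SKBR3 to MCF7 seen for AKTIP, 0.666 (95% interval 0.593 to 0.74). Genes lower in MCF7 had a slope of 0.302 (0.261 to 0.342), which their choice in MCF7 lowers. The 150 lowest genes chosen in 1 MCF7 replicate, at a CPM cut of 20, and measured in the other had a ratio of means of 0.375 (0.311 to 0.441). In these libraries such an effect therefore does not account for the set as a whole. The interval of AKTIP is for 1 gene and the others are for sets of genes, so they do not measure the same spread. For genes that carry the heptamer described under the other observations the values are split and leave the dose open: the ratio was 0.524 (0.397 to 0.66) over all 146 carriers, 0.462 (0.377 to 0.548) over the 34 lower in MCF7, 0.644 (0.571 to 0.716) over the 15 lower in SKBR3, and 0.517 (0.425 to 0.606) over the 30 lowest chosen in one replicate and measured in the other. A dose effect that is not proportional between AKTIP and other genes and a biological difference between the lines, such as receptor status, stay open and were not tested.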

How the results depend on the processing

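The counts without carriers of the heptamer were chosen only after the data were seen. AKTIP fell in both lines in every alternative, by -2.75 to -2.47 in MCF7 and -1.84 to -1.63 in SKBR3 when single libraries were left out. With single libraries left out, changed genes ranged from 312 to 702 in MCF7 and from 68 to 238 in SKBR3, genes that differed between the lines from 65 to 216, shared genes from 22 to 51, and called lists from 2 to 8 and from 0 to 4. A 2-fold threshold left 17, 12, 11 and 1 genes in MCF7, SKBR3, the difference and the shared set; the shared one was AKTIP. The DESeq2 Wald test called 424 genes in MCF7, of which 415 were also called by edgeR. Without a low-count filter, 211 genes differed between the lines and 0 lists were called in SKBR3. An estimated correlation left 0 lists in either line, and fry left 0 in SKBR3. Leaving out carriers of the heptamer gave 30 shared genes, with fewer genes tested. Other than for the fold threshold and the carriers, the cause was not tested.

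Replicates with the same number correlated at 0.063 in MCF7 and -0.011 in SKBR3 across genes, after each group was centred. With 2 libraries per group, both pairs of a line give the same value. The correlation therefore cannot settle whether replicates of the same number were paired. With the replicate number as a block, 323 genes were called in SKBR3, 267 differed between the lines, 78 were shared, and 0 lists were called in SKBR3; MCF7 had 950.

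Of the named calls, 33 of 88 in MCF7, 11 of 46 in SKBR3 and 7 of 7 in the difference held in every alternative run on single genes, which leaves out the 2-fold threshold. SERPINA5 in MCF7 is counted as held although the DESeq2 Wald test gave it no adjusted p. VPS8 was called in MCF7, but its edgeR adjusted p rounds to 0.05 and it is left out of the 88. Where its call was lost without a library, it is included in the MCF7 counts that follow. The named MCF7 calls lost without a library were 33 and 27 for mock replicates 1 and 2, and 38 and 43 for siAKTIP replicates 1 and 2. In SKBR3 they were 25 and 22 for the mock and 20 and 24 for the siAKTIP replicates. The DESeq2 Wald test lost 20 and 9. Genes that did not pass changed sign when single libraries were left out: in MCF7 PGR (-0.0221 to 0.0615), JAK2 (-5e-04 to 0.1654), CAND1 (-0.0299 to 0.0449) and SOCS3 (-0.0076 to 0.2389), and in SKBR3 ESR1 (-0.9137 to 0.1407), CUL2 (-0.1176 to 0.0452), ERBB2 (-0.0235 to 0.0286) and STAT3 (-0.0551 to 0.0225). With 2 libraries per group, changes under about 1.5-fold are recovered only in part.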

Other observations

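Several further gene groups held changed members although camera called none of their lists. In MCF7, luminal markers shifted both ways: KRT8 (-0.10 ± 0.02), KRT19 (-0.13 ± 0.03), CLDN7 (-0.19 ± 0.04) and ELF3 (-0.15 ± 0.04) were among 6 of 25 that fell, and 1 rose (adjusted over the list alone, 6 rose and 8 fell). Cholesterol synthesis had 3 of 24 lower, IDI1 (-0.21 ± 0.05), DHCR7 (-0.19 ± 0.04) and TM7SF2 (-0.22 ± 0.05), and in SKBR3 IDI1 fell as well (-0.24 ± 0.05). Adjusted over the list alone, 1 rose and 5 fell in MCF7 and 3 fell in SKBR3. PI3K-AKT components had 3 of 26 higher in MCF7, the phosphatase PHLPP2 (0.24 ± 0.06), TSC1 (0.17 ± 0.04) and PIK3R1 (0.12 ± 0.04), with 6 higher adjusted over the list alone, and edgeR and DESeq2 called 0 in SKBR3, with 2 at an unadjusted p under 0.05. Among 23 FOXO targets TXNIP (0.32 ± 0.03) was among 2 that rose in MCF7 and 2 fell, and adjusted over the list alone 5 rose and 3 fell. In the HOPS, CORVET and endosomal fusion list, RAB5B was among 2 of 20 that fell in MCF7 and was the 1 that fell in SKBR3; adjusted over the list alone, 2 fell in MCF7, and 1 rose and 2 fell in SKBR3, and fry called this list in MCF7 (adjusted p = 0.0471). Of 17 shelterin and telomere genes, to which AKTIP has been linked, edgeR and DESeq2 called 0 in both lines, with 4 at an unadjusted p under 0.05 in each.

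In the motif tests that follow, the UTR trend test, the test of seed pairing on SKBR3 genes, the hexamer counts and the regressions for lists other than the estrogen receptor-induced one were chosen only after results were seen. The prediction on microRNA sites was written after the fold changes of single genes had been seen and before the motif search was run, and the predictions on the estrogen receptor-induced genes after the search and before their regression. A minority of the transcripts that fell after siAKTIP carried the same short motif, 37 of 327 searched genes in MCF7 and 16 of 68 in SKBR3. Among searched genes lower by at least 1.5-fold in MCF7, 10 of 16 carried it. This count describes the genes and is no test, as the motif was chosen on these fold changes. Of 16384 heptamers, GCGACTT had the strongest downward shift of its carriers in both lines, by a one-sided rank-sum test across genes (MCF7 n = 10150 genes, z = -8.41, Bonferroni p = 3.25e-13; SKBR3 n = 9644 genes, z = -6.39, Bonferroni p = 1.34e-06). Genes are not independent replicates, so these p values rank heptamers and do not cover variation between cultures. The log2 fold change was negative in 113 of 161 carriers in MCF7 (median -0.08) and in 103 of 151 in SKBR3 (median -0.05). The same heptamer lies in the AKTIP transcript at 53492414 to 53492420 of chromosome 16 (GRCh38, minus strand), in exon 11 of 11, across the last 6 coding bases and the first base of the stop codon, in the context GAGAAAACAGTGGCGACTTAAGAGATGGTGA (53492402 to 53492432). By itself that is weak evidence, since 2192 heptamers (13.4%) occur in AKTIP. It was carried by 12 of 25 searched genes lower in both lines, AKTIP left out, against 1.52% of other genes, an odds ratio of 51.97 (21.86 to 123.55) within classes of UTR length and expression, which describes the genes and does not test the motif, as the heptamer was chosen on these same fold changes. RAB5B, PERP, ARPC4, MT2A, B3GALT6 and SFXN4 carry it, and of the 9 lowest named genes besides AKTIP 7 do in MCF7 and 6 in SKBR3. The G2/M gene SPC24, which fell in MCF7, carries it as well. So does AGO2, which rose in both lines (0.16 in MCF7 and 0.21 in SKBR3).

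Chosen in MCF7 without the genes lower in SKBR3, the heptamer was again GCGACTT (z = -6.93), and its odds ratio among the 68 searched genes lower in SKBR3 was 20.86 (11.08 to 39.27), which is consistent with siRNA seed pairing, in which bases near the 5' end of an siRNA repress unintended transcripts. The siRNA sequence is not given, so the match to its seed remains a hypothesis. It does not cover most lower genes: in MCF7, 290 of 327 searched lower genes lack the heptamer, among them ESYT2, CERK and NNT. For genes lower in MCF7 and without the heptamer, either of its hexamers (without its first or its last base) gave an odds ratio of 1.83 (1.24 to 2.69). The heptamer was chosen on these MCF7 fold changes, so this value describes the genes and is no separate test. For genes lower in SKBR3 the odds ratio was 1.25 (0.52 to 3.04), an interval that includes 1. In the reverse split, SKBR3 without the genes lower in MCF7, no heptamer passed: GAGATAA came first (z = -4.10, Bonferroni-adjusted 0.334) and GCGACTT ranked 5 (z = -3.64), so the SKBR3 signal rests partly on shared genes. Effects of AKTIP loss and of the siRNA itself on carriers of the heptamer, such as RAB5B and PERP, are confounded by the design.

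Genes that rose in MCF7 tended to carry sites of microRNAs abundant in epithelial cells. Sites of 19 such families had a median percentile of 99.5 for upward shift among heptamers of the same base composition. Of these families, 19 of 19 were above 50 (one-sided exact sign test p = 1.91e-06, the smallest it can give). The median of 8 families of other tissues was 83.2 (one-sided permutation p = 3e-05 for the difference of means). In SKBR3 the medians were 98.7 and 76.6 (one-sided permutation p = 6.3e-04 for the difference of means). From genes with sites of 0 families to those of 10 to 19, however, the share called higher in SKBR3 went from 0.93% to 0.75%. The median log2 fold change went from -0.0055 to 0.0015. In MCF7, with UTR length not accounted for, these values went from 0.8% to 10.55% and from -0.0413 to 0.0546. The MCF7 values are consistent with weaker repression by the cell's own microRNAs after siRNA uptake, a hypothesis tested on the data that raised it. A trend with UTR length and GC content predicted a median of 50 or less after both were regressed out. The median was 99.5 (exact sign test, 1.91e-06). These are the same values as above, known before this prediction was written, so they are no separate test of the trend. They argue against it only as far as the regression removed it. The sign test takes 19 families as independent, although their sites can overlap, as those of miR-19 and miR-130 do. Of 8 other-tissue families 6 also lay above 50, so 50 may not be the right baseline, and the cause was not tested. As any siRNA could compete for Argonaute, and DICER1, TNRC6A and AGO2 rose, an effect of siRNA load cannot be separated from AKTIP loss without a non-targeting control.

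The rise of estrogen receptor-induced genes in MCF7 was then tested against the same trends, with a negative outcome for both. The call of this list did not hold with an estimated correlation (camera adjusted p = 0.467) or when any 1 of 3 MCF7 libraries was left out. The mean log2 fold change of 45 members was 0.0753 ± 0.0278 (SE), 0.0696 ± 0.0275 after UTR length, GC content and expression were regressed out, and 0.069 ± 0.0273 after the number of microRNA families was added, which is 2.53 standard errors above 0 in both cases. Neither trend therefore accounts for the mean shift of these genes in these libraries. The SE is taken across members and does not cover variation between cultures. For the lists called lower in MCF7, the same regression moved the mean of oxidative phosphorylation genes from -0.0458 to -0.0268 and that of ribosomal proteins from -0.0235 to -0.0108, while G1/S genes kept -0.0599 of -0.0703. Ribosomal proteins thereby went from -4.93 to -2.14 standard errors, and to -1.79 with microRNA families added. With these families added, oxidative phosphorylation genes stood at -2.24 and G1/S genes at -5.34 standard errors. The integrated stress list went from -0.0226 (-1.24 standard errors) to -0.0097 (-0.59), and G2/M genes from -0.0463 to -0.0354 (-2.12 standard errors, and -1.88 with microRNA families added).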
